A study of Mus musculus with 17 samples.

How the data were processed

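Poly(A) RNA of sorted splenic CD4+ T cells was sequenced from 17 Ldlr-/- mice in 3 diet groups, 5 on a normal cholesterol diet (NCD), 6 on a high cholesterol diet (HCD) and 6 switched from the high to the normal diet (DS). Per the labels' protocols, spleens were meshed, erythrocytes were lysed, and CD3+CD4+CD8-CD19-CD25- cells were sorted on a FACSAria II. Total RNA was isolated with a DNase step, and libraries were made with the KAPA mRNA HyperPrep kit. The samples were mapped to groups by their titles, which also number the mice within a group. No label gives a sequencing date, batch, litter, sex or age.

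The authors deposited a single table of raw read counts per transcript, whole numbers without normalisation, with 35745 RefSeq transcript rows and 17 sample columns. All columns matched a sample title. The submitters' processing notes name CASAVA 1.8.2, STAR 2.5.2b and the mm10 build. The counting tool, the annotation release, the use of strand and the treatment of multi-mapping reads are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical paralogs therefore cannot be told apart in these counts.

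Transcript accessions were paired with gene symbols through a RefSeq gene table of the matching assembly, GRCm38.p6 (35440 rows), and through GENCODE metadata of release M21 (188 rows). The 117 unmatched rows held 0.543% of all counts, from 0.282% to 2.192% per sample, and were counted but not named. Coordinates are 1-based, on mm10, and span the gene. The isoform rows of a gene repeated the same reads: over 3251 genes with several rows and a total of at least 1000, the lower isoforms had a median of 0.981 of the highest isoform's total, and 78.3% of them reached 90%. Summing such rows would count reads more than once. The row with the highest total over all samples was therefore kept for each gene, which left 24562 genes. This choice was made after the table was seen, and the sum over rows and the use of every row were run as alternatives.

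Total counts over the kept rows were 2691946 to 14759774 per library, or 4680816 to 25593282 over all rows as deposited, and the shallow libraries limit what can be detected for low genes. No 2 libraries of a group were copies: over 40 pairs within groups, none was identical, and the chi-square per degree of freedom over genes with at least 20 counts was 2.21 to 22.4. The 17 samples are separate mice by the series' design text.

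Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 11433 genes and dropped 13129. Libraries were scaled by TMM, with factors from 0.972 to 1.02. One model with the 3 groups as terms and no covariates was fitted by glmQLFit with robust estimation, and glmQLFTest gave the 3 pairwise contrasts and a test for any difference. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold change. The common biological coefficient of variation was 0.105. The standard error of a log2 fold change was taken as its size over the square root of the F statistic. Normalised counts (CPM) were computed from the deposited counts and the TMM library sizes and are given as mean ± SD over mice.

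Before the data were examined, 31 gene lists were fixed for interferon responses, helper subsets, activation, lipid and energy metabolism, stress and other cell types. Of these, 28 had at least 2 tested members and were tested against all other genes by camera in limma 3.58.1, with a preset correlation of 0.01. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction, were run as alternatives. The mixed test of fry, which asks whether members differ in either direction without comparing them with other genes, was also run. The list of mitochondrially encoded transcripts had 0 members in the table. Members were also counted by edgeR p-values adjusted over the list alone. A list score, the mean log2 CPM of the tested members of a list (prior count 2), was computed per mouse from the deposited counts. Scores were compared by two-sided exact permutation tests, adjusted over 90 tests. The smallest p this can give is 0.00216, so a single score could not pass the adjustment over 90 tests alone.

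The genes named in the text were chosen by a rule fixed in advance: for each comparison up to 8 genes per direction with the smallest p and up to 4 with the largest fold change among called genes, or the 4 of smallest p per direction where no gene was called; up to 3 members per direction of each list that passed, or the best member where none did; and 25 genes of known function named beforehand. A list member was taken to pass if its p, adjusted over all genes or over the list alone, was under 0.05. Bank1, Cr2 and Cd79a in the B cell list fall under this rule. Not every gene the rule selects is given in every comparison. Of the 25 genes, Ccr5, Gata3, Sell, Cd44, Mki67 and Il2ra are not described below, and none of them was called over all genes.

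The fit was tested on simulated counts with the real means, dispersions and library sizes. In the HCD and NCD comparison, over 5 runs with 200 changed genes each among 11433, changes of 1.25-fold, 1.5-fold and 2-fold were recovered in 31.9%, 74.9% and 90.3% of cases, and 40 unchanged genes were called in all runs together. In DS against NCD, where nothing was changed, 1 gene was called. A list of 30 genes raised 1.15-fold was called by camera in 5 of 5 runs, and 0 of 95 unchanged lists were called. Simulated genes vary independently of each other, so this does not test the preset correlation.

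Alternatives set before the data were examined were DESeq2 size factors and upper quartile scaling, no filter and a mean of at least 1 CPM, fitting without robust estimation, DESeq2 1.42.0 and limma-voom with sample weights, only the 2 groups compared, the title number as a block, scores of B cells and monocytes as covariates, a minimum log2 fold change of 0.58 and leaving out each mouse. A surrogate variable from sva 3.50.0, the follicular helper score, library size and title number as covariates, and a fit without NCD 4 and DS 2, were added after the data were seen. For each comparison the model was also refitted to 100 splits of the same mice, the real grouping among them.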

Results

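RNA sequencing was performed on splenic CD4+ T cells from 17 mice of an Ldlr-/- strain, which lacks the low-density lipoprotein receptor and is widely used to raise plasma cholesterol by diet. A normal cholesterol diet (NCD) was given to 5 mice and a high cholesterol diet (HCD) to 6 mice, and a further 6 mice were switched from the high to the normal cholesterol diet (DS). Cells were sorted as CD3 and CD4 positive and as negative for CD8, CD19 and CD25, a gate that leaves out CD8 T cells, B cells and cells with surface IL-2 receptor alpha. The series addresses whether hyperlipidemia changes the interferon program of CD4 T cells, and the DS group addresses whether the difference remains after the diet is normalised. With 1 row kept per gene, the total count per library ranged from 2691946 (DS 2) to 14759774 (HCD 1), and 12925 to 14758 genes had at least 1 count. After filtering, 11433 genes were tested.

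The sorted cells carried the transcripts of CD4 T cells in all 3 groups. Cd4 was measured at 1306 ± 45.6 CPM in NCD (SD, n = 5), 1342 ± 26.9 CPM in HCD (SD, n = 6) and 1322 ± 50.2 CPM in DS (SD, n = 6). The T cell identity list differed by 0.01 ± 0.03 (SE, mean log2 CPM) between HCD and NCD (exact permutation p = 0.617, two-sided) and by -0.03 ± 0.03 between DS and HCD (exact permutation p = 0.359). Cd8a and Cd19 lay below the count filter. Ldlr, the gene disrupted in the strain, still collected reads, at 57.5 ± 5.04 CPM in NCD, 67.9 ± 9.03 CPM in HCD and 45.9 ± 9.04 CPM in DS (SD). All mice share the strain, so this gene checks no group label, and counts per gene do not show whether the disrupted exon was read. B cell transcripts were mostly low but not evenly spread: the B cell list score was 4.57 (mean log2 CPM) in NCD 1 and 2.13 to 2.66 in the other NCD mice. Some members of other-cell lists were not low, such as Ctss of the monocyte list at 213 CPM in NCD.

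Between HCD and NCD, 6 genes differed and all were higher in HCD (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 4 belong to the interferon lists and 1 to the list of sterol-responsive genes. Scd2, a stearoyl-CoA desaturase that makes monounsaturated fatty acids (chromosome 19, 44293676 to 44306864, mm10), was measured at 232 ± 25.1 CPM in HCD (SD, n = 6) and 158 ± 15.0 CPM in NCD (SD, n = 5), a log2 fold change of 0.55 ± 0.09 (SE, edgeR adjusted p = 0.00974). Irgm2, an interferon-inducible GTPase (chromosome 11, 58214977 to 58222783), rose by 0.43 ± 0.07 on the log2 scale, from 133 ± 9.91 to 179 ± 15.9 CPM (edgeR adjusted p = 0.0145). Tgtp2, a GTPase of the same class (chromosome 11, 49057196 to 49064212), rose by 0.49 ± 0.09, from 35.4 ± 3.02 to 49.7 ± 6.33 CPM (edgeR adjusted p = 0.0321). Tgtp2 has a near-identical neighbour, Tgtp1, and their reads may have been divided between them. Irf9, the DNA-binding partner of STAT1 and STAT2 downstream of the type I interferon receptor (chromosome 14, 55603985 to 55610030), rose by 0.32 ± 0.06, from 172 ± 7.01 to 214 ± 12.1 CPM (edgeR adjusted p = 0.0321). Usp18, a protease that removes ISG15 and dampens type I interferon signalling (chromosome 6, 121245906 to 121270917), rose by 0.52 ± 0.10, from 29.0 ± 5.60 to 41.3 ± 3.96 CPM (edgeR adjusted p = 0.0469). Tnfaip8, a TNF-induced regulator of cell death (chromosome 18, 49979427 to 50093229), rose by 0.39 ± 0.08, from 89.8 ± 6.23 to 118 ± 13.6 CPM (edgeR adjusted p = 0.0491). Each of the 6 genes was above the NCD mean in 6 of 6 HCD mice. No gene was called lower by edgeR, while 486 genes were lower at an unadjusted p under 0.05, DESeq2 called 4 genes lower and limma-voom with sample weights called 1.

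**Figure D1:**
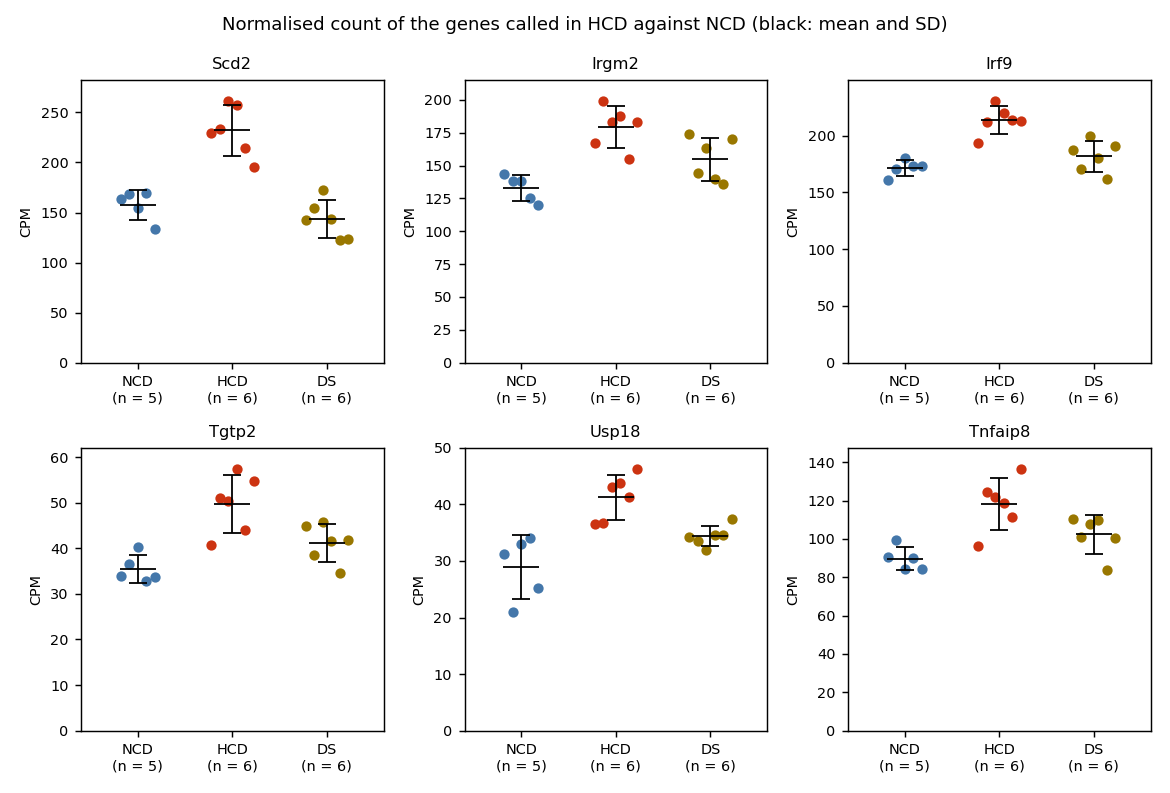
Normalised count (CPM, y axes from 0) of the 6 genes called in HCD against NCD, in each mouse of the NCD (n = 5), HCD (n = 6) and DS (n = 6) groups. Points are mice, and black bars are the group mean and SD. Scd2 averaged 158 CPM in NCD, 232 CPM in HCD and 143 CPM in DS, whereas the DS means of the other 5 genes lay between those of NCD and HCD.

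The interferon lists held 4 of the 6 genes called higher. Of 56 tested members of the type I interferon response list, 21 rose and 0 fell in HCD when p-values were adjusted over the list alone, against 2 over all genes tested, and 51 members had a fold change above 0 (median log2 fold change 0.22). Ifi27l2a, an interferon-induced membrane protein, rose by 0.64 ± 0.12 (edgeR adjusted p = 0.000624 over the list alone and 0.0546 over all genes). Irf7, the transcription factor that amplifies type I interferon production, rose by 0.40 ± 0.10 (edgeR adjusted p = 0.00233 over the list alone), and Stat1 by 0.23 ± 0.07 (edgeR adjusted p = 0.0153 over the list alone). Isg15 (0.10 ± 0.15) and Ifit3 (0.37 ± 0.25) did not pass. Of 36 tested members of the interferon gamma response list, 11 rose and 0 fell when adjusted over the list alone, against 2 over all genes (median 0.15), among them Igtp, another interferon-inducible GTPase, by 0.37 ± 0.08. Gbp2 did not pass (0.24 ± 0.11). Ifng itself was low, at 4.40 ± 1.76 CPM in HCD and 3.91 ± 1.19 CPM in NCD (SD), and did not pass.

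Against all other genes, the camera test with a preset correlation gave adjusted p = 1.58e-22 for the type I list and 2.71e-19 for the interferon gamma list. With an estimated correlation, the adjusted p = 0.151 for the type I list and 0.151 for the interferon gamma list, so neither call held. Per mouse, the type I score was 0.24 ± 0.11 (SE) higher in HCD (exact permutation p = 0.0433, adjusted 0.390 over 90 score tests) and the interferon gamma score 0.25 ± 0.08 higher (exact permutation p = 0.0108, adjusted 0.227). All 6 HCD mice exceeded the NCD mean on both scores. The groups overlapped: NCD 4 (6.19) and NCD 5 (6.05) lay inside the HCD range of the type I score (5.98 to 6.26), and NCD 1 (6.65) and NCD 4 (6.68) inside that of the interferon gamma score (6.60 to 6.93).

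**Figure D2:**
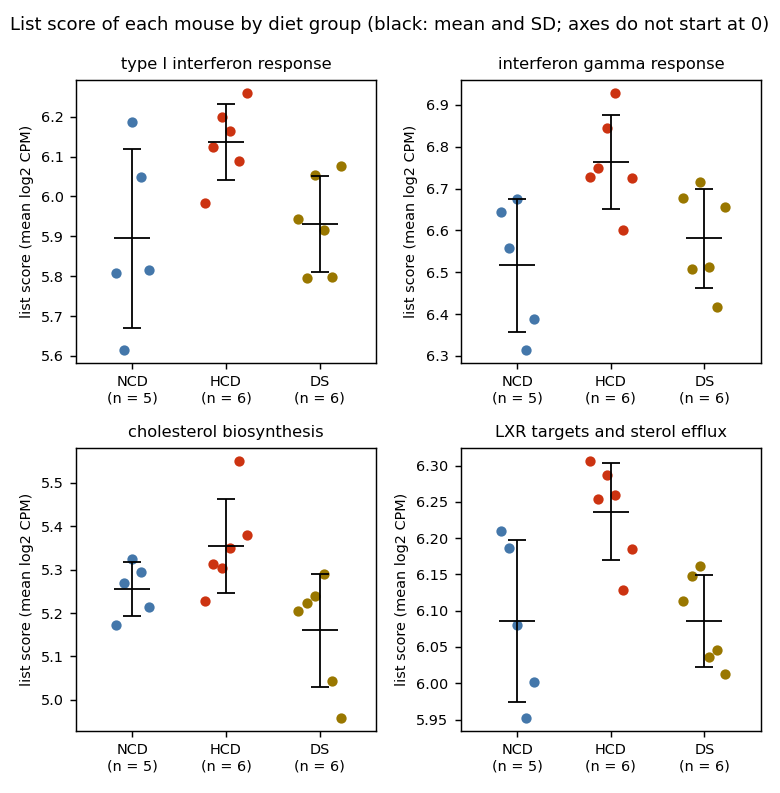
List score (mean log2 CPM of the tested members, y axes not from 0) for the type I interferon, interferon gamma, cholesterol biosynthesis and LXR lists in each mouse, by diet group. Points are mice, and black bars are the group mean and SD. The type I interferon score averaged 5.89 in NCD, 6.14 in HCD and 5.93 in DS, and the cholesterol biosynthesis score 5.25, 5.35 and 5.16.

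Few other lipid genes passed beside Scd2 in this comparison. Fold changes were above 0 for 15 of 17 tested LXR targets and sterol efflux genes and for 19 of 23 cholesterol biosynthesis genes. The LXR score was 0.15 ± 0.06 (SE) higher in HCD (exact permutation p = 0.0238, adjusted 0.281). The cholesterol biosynthesis score was 0.10 ± 0.05 higher (exact permutation p = 0.0931, adjusted 0.415). Among 17 tested LXR targets and sterol efflux genes, 2 rose when adjusted over the list alone, Scd2 and Myo1e (0.66 ± 0.20), and 1 over all genes (camera adjusted p = 0.000104, and adjusted p = 0.151 with an estimated correlation). The cholesterol exporters Abca1 (0.67 ± 0.23) and Abcg1 (0.17 ± 0.07) did not pass, with edgeR adjusted p = 0.0659 and 0.0662 over the list alone. Of 23 tested cholesterol biosynthesis genes, 1 rose when adjusted over the list alone, Hmgcr, which encodes the rate-limiting reductase of the pathway (0.22 ± 0.07), against 0 over all genes (camera adjusted p = 0.00032, and adjusted p = 0.318 with an estimated correlation). Cpt1a, the carnitine transferase that admits fatty acids to mitochondria, rose by 0.75 ± 0.19 within the fatty acid oxidation list (edgeR adjusted p = 0.0266 over the list alone), whose 21 tested members were not called together (camera adjusted p = 0.111).

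Several lists of helper subsets were higher in HCD by camera with the preset correlation, with few single members passing. Of 22 tested Th1 genes, 3 rose when adjusted over the list alone: Tbx21, the Th1 master regulator, by 0.43 ± 0.13, Nkg7 by 0.67 ± 0.18 and Hopx by 0.40 ± 0.12. Of 10 tested Th17 genes, 2 rose, Stat3 (0.23 ± 0.08) and Tmem176a (0.61 ± 0.22), while Rorc, the Th17 master regulator, did not pass (0.32 ± 0.25). No member of the follicular helper (17 tested), regulatory T cell (21 tested) or inhibitory receptor (16 tested) lists passed. Their best members were Pdcd1 (0.81 ± 0.33), Nt5e (0.50 ± 0.20) and Tnfsf8 (0.27 ± 0.10), and Bcl6 (0.20 ± 0.13) and Foxp3 (0.15 ± 0.14) did not pass. The sort left out cells with surface IL-2 receptor alpha, whose gene Il2ra is in the regulatory list. The regulatory list and Foxp3 therefore describe only the cells that remained. Of 22 tested naive T cell genes, 2 fell when adjusted over the list alone, S1pr1, the receptor for exit from lymphoid organs, by 0.30 on the log2 scale and Trib2 by 0.21. With the preset correlation, camera called the Th1 (adjusted p = 4.6e-08), Th17 (2.65e-05), follicular helper (7.31e-07), regulatory (2.31e-05), inhibitory receptor (0.000655) and effector memory (0.00505) lists higher and the naive list lower (1.45e-06). With an estimated correlation none of these 7 was called, with adjusted p = 0.151, 0.151, 0.250, 0.319, 0.301, 0.309 and 0.248 in the same order. The follicular helper score ranged from 4.86 to 6.01 in HCD and from 4.47 to 5.45 in NCD, and did not pass (exact permutation p = 0.102). These list calls did not hold with a surrogate variable as a covariate: the regulatory list was called in the opposite direction (camera adjusted p = 0.00544), the follicular helper and inhibitory receptor lists turned without being called (0.871 each), and the Th1, Th17, effector memory and naive lists were not called. The variable was estimated from the same libraries and correlated within groups with these scores (r = -0.83 for regulatory, -0.815 for follicular helper and 0.757 for naive). That fit therefore removes part of what it tests and cannot decide whether diet shifts these lists.

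**Figure D3:**
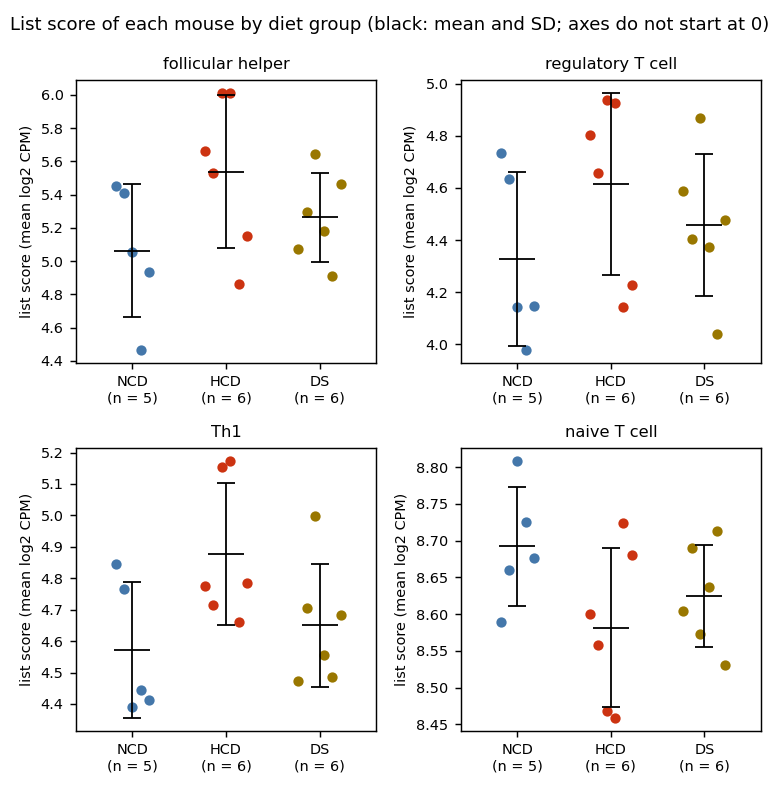
List score (mean log2 CPM of the tested members, y axes not from 0) for the follicular helper, regulatory T cell, Th1 and naive T cell lists in each mouse, by diet group. Points are mice, and black bars are the group mean and SD. The follicular helper score averaged 5.06 in NCD, 5.54 in HCD and 5.26 in DS, with SDs of 0.40, 0.46 and 0.27.

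Metabolic, proliferation and other-cell lists were also compared between HCD and NCD. With the preset correlation, proliferation (adjusted p = 0.00175), glycolysis (0.00146) and heat shock and dissociation stress (0.00487) were called higher, with adjusted p = 0.309, 0.248 and 0.375 with an estimated correlation and no member passing. The heat shock call ended without HCD 6 or without NCD 5, whose scores of 6.85 and 5.09 lay apart from their groups, and 3 of 6 HCD mice were above the NCD mean. The B cell list was called lower (adjusted p = 0.00119, and adjusted p = 0.318 with an estimated correlation). Of its 9 tested members, 2 fell when adjusted over the list alone, Cr2 by 1.83 and Cd79a by 0.95 on the log2 scale. Cr2, complement receptor 2, was at 12.2 CPM in NCD 1 and 0.774 to 2.94 CPM in the other NCD mice, and without NCD 1 the list was not called (adjusted p = 0.773). Not called as lists were Th2 (camera adjusted p = 0.370), TCR immediate early genes (0.140), oxidative phosphorylation (0.514), plasma cell (0.494), NK cell (0.688), monocyte and macrophage (0.851), dendritic cell (0.918), erythroid (0.738), platelet and megakaryocyte (0.228), stroma and endothelium (0.117), sex chromosome transcripts (0.677) and T cell identity (0.701). Within them, Nfkbia, the inhibitor of NF-kB, rose by 0.29 ± 0.07, and Il17rb, Itgb3 and Pecam1 fell by 0.63, 0.19 and 0.27 when adjusted over their lists alone. The CD8 and neutrophil lists had 1 tested member each, Cd8b1 (-0.04 ± 0.14) and Mmp9 (0.04 ± 0.42).

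The count of 6 genes depended on single libraries. It moved by over 1.5 times without NCD 1 (2 genes), NCD 2 (19), NCD 4 (12), NCD 5 (2), NCD 6 (0), HCD 3 (1), HCD 4 (1), HCD 5 (17), HCD 6 (2), DS 1 (10) or DS 4 (2), and DESeq2 called 25 genes, including all 6, of which 13 were interferon list members. The call ended for all 6 genes with the follicular helper score as a covariate (0 genes) and for all but Scd2 when counts were summed over the rows of a gene (1 gene). With the follicular helper score the log2 fold changes were still above 0, at 0.44 for Scd2, 0.34 for Irgm2, 0.43 for Tgtp2, 0.29 for Irf9, 0.57 for Usp18 and 0.37 for Tnfaip8.

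Between DS and HCD, Scd2 was the 1 gene called over all genes tested. This comparison shares its HCD libraries with HCD against NCD, so genes that rose there tend to fall here even without an effect. Scd2 fell by 0.70 on the log2 scale (SE 0.08, edgeR adjusted p = 7e-05), from 232 ± 25.1 CPM in HCD to 143 ± 18.9 CPM in DS (SD, n = 6 each), and 6 of 6 DS mice were below the HCD mean. No gene was called higher by edgeR, while 438 were higher at an unadjusted p under 0.05 and DESeq2 called 3 higher. Of 23 tested cholesterol biosynthesis genes, 12 fell and 0 rose when adjusted over the list alone, against 0 over all genes (median -0.23). Cyp51, the lanosterol demethylase, fell by 0.48 (SE 0.10), Hmgcr by 0.28 (SE 0.06), Insig1, the sterol-sensing retention protein, by 0.34 (SE 0.09) and Sqle, the squalene epoxidase, by 0.37 (SE 0.12). Camera gave adjusted p = 9.23e-13 for the list, and adjusted p = 0.174 with an estimated correlation. The score fell by 0.19 (SE 0.07, exact permutation p = 0.00649, adjusted 0.227). Of 17 tested LXR targets, Scd2, Abca1 and Abcg1 fell, the latter pair by 0.83 (SE 0.23) and 0.25 (SE 0.06) when adjusted over the list alone, and the score fell by 0.15 (SE 0.04, exact permutation p = 0.00649, adjusted 0.227). Camera gave adjusted p = 1.68e-05, and adjusted p = 0.170 with an estimated correlation. Ldlr, itself controlled by the sterol-sensing SREBP2, differed by -0.59 ± 0.12 but did not pass (edgeR adjusted p = 0.166). Ldlr, Hmgcr and Cyp51 were called over all genes by DESeq2 and with library size as a covariate, but not by limma-voom.

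Part of the interferon genes were lower in DS than in HCD when adjusted over their lists alone. Because the HCD libraries are shared, this fall is not independent of the rise in HCD against NCD. Of 56 type I list members, 10 fell and 0 rose when adjusted over the list alone, against 0 over all genes (median -0.18). Lgals3bp fell by 0.31 (SE 0.06), Ifi27l2a by 0.53 (SE 0.11), Irf7 by 0.39 (SE 0.09), Irf9 by 0.23 (SE 0.06), Isg15 by 0.42 (SE 0.15) and Stat1 by 0.20 (SE 0.07). Of 36 interferon gamma list members, 10 fell and 0 rose when adjusted over the list alone, against 0 over all genes (median -0.15), including Igtp by 0.26 (SE 0.07), Gbp10 by 0.64 (SE 0.19) and Tap1, the peptide transporter of antigen presentation, by 0.17 (SE 0.06). Gbp10 shares sequence with other guanylate-binding protein genes. Camera gave adjusted p = 1.7e-15 and 3.15e-12 for the 2 lists, and adjusted p = 0.265 and 0.174 with an estimated correlation. The type I score fell by 0.21 (SE 0.06, exact permutation p = 0.0108, adjusted 0.227) and the interferon gamma score by 0.18 (SE 0.07, exact permutation p = 0.0260, adjusted 0.281).

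Single members of other lists passed after the switch. When p-values were adjusted over their lists alone, Ccr6, a Th17 chemokine receptor, fell by 0.65, Nfkbia by 0.28, and the glycolytic genes Aldoc and Tpi1 by 0.75 and 0.31. The naive T cell list was mixed: Trib2 and Als2cl rose by 0.24 and 0.21, and Ly6c1 fell by 0.30. The Y-linked genes Ddx3y and Uty rose by 0.22 and 0.28. The tested members of the sex chromosome list, Ddx3y, Uty, Kdm5d and Eif2s3y, are all Y-linked. Their score ranged from 6.50 (HCD 4) to 6.94 (DS 6, mean log2 CPM) over all mice. Y-linked transcripts were thus read at similar levels in every mouse, which argues against a mixture of sexes as the cause of these rises. Tbx21 (-0.23 ± 0.13), Cxcr3 (-0.26 ± 0.22) and Foxp3 (-0.09 ± 0.13) did not pass. Camera with the preset correlation called 14 lists lower and 2 higher, the latter being naive T cell (adjusted p = 0.0379) and sex chromosome transcripts (0.00103), and called none with an estimated correlation, where the smallest adjusted p = 0.170. Beside the interferon, cholesterol biosynthesis and LXR lists, those lower by the preset test were Th1 (7.6e-05), follicular helper (0.0024), regulatory (0.00497), effector memory (0.00287) and inhibitory receptor (0.0484). The rest were TCR immediate early (0.000455), proliferation (0.0379), glycolysis (0.0193), oxidative phosphorylation (0.000316) and heat shock and dissociation stress (0.0308). The count of 1 gene rose to 4 without HCD 1 or DS 3, to 9 with library size as a covariate and to 15 with DESeq2, and Scd2 passed in each of these.

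No gene was called between DS and NCD by edgeR. At an unadjusted p under 0.05 there were 688 genes, against 572 by chance, DESeq2 called 1 gene and limma-voom called 0. The smallest adjusted p was 0.273, for Rundc3b (0.47 ± 0.10) and Ddx3y (0.34 ± 0.07), and neither passed over all genes. Ddx3y was the 1 member of the sex chromosome list that passed over the list alone. Scd2 was at 143 ± 18.9 CPM in DS and 158 ± 15.0 CPM in NCD (SD), a log2 fold change of -0.15 ± 0.09 (edgeR adjusted p = 0.843). No member of the interferon, Th1, Th17, follicular helper, regulatory, cholesterol biosynthesis or LXR lists passed over the list alone, and Irf7 (0.02 ± 0.10), Stat1 (0.03 ± 0.07) and Hmgcr (-0.06 ± 0.07) differed by less than their errors. The members of the interferon and cholesterol biosynthesis lists closest to passing by edgeR were Irgm2 (0.22 ± 0.07, edgeR adjusted p = 0.205 over the list alone), Parp14 (0.20 ± 0.08, edgeR adjusted p = 0.383 over the list alone) and Fdft1 (-0.26 ± 0.11, edgeR adjusted p = 0.271 over the list alone). The type I score differed by 0.04 ± 0.11 (exact permutation p = 0.729) and the LXR score by 0.00 ± 0.06 (exact permutation p = 0.998). A missed threshold does not show that DS and NCD were equal: of simulated genes with the smallest change tried, 31.9% were recovered in the HCD and NCD comparison. Of 9 tested B cell genes, Cr2, Bank1 and Cd79a fell by 2.13, 0.87 and 0.95 when adjusted over the list alone, and without NCD 1 this list was not called (camera adjusted p = 0.136). Camera with the preset correlation called 9 of 28 lists. Type I interferon (adjusted p = 0.0358, median log2 fold change 0.04), interferon gamma (0.0208, median 0.05), Th17 (0.0208), follicular helper (0.0373) and sex chromosome transcripts (0.0168) were higher in DS, and cholesterol biosynthesis (0.00877, median -0.11), naive T cell (0.00877), oxidative phosphorylation (0.0143) and B cell (2.28e-05) were lower. The type I call ended without NCD 1, NCD 6, DS 3 or DS 6 and turned without NCD 2 (adjusted p up to 0.89), the interferon gamma call ended without NCD 5, NCD 6, DS 1, DS 3 or DS 6 (up to 0.746), and the cholesterol biosynthesis call ended without NCD 5, DS 5 or DS 6 (up to 0.207). With an estimated correlation none was called, and the adjusted p = 0.868, 0.844 and 0.844 for the type I, interferon gamma and cholesterol biosynthesis lists.

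The 6 genes called between HCD and NCD were all lower in DS than in HCD. Of these, 1 (Scd2) was also called in DS against HCD in the opposite direction, 0 were called in DS against NCD, and 5 were called in neither. In DS, the 5 other genes kept between 0.261 (Irf9) and 0.519 (Irgm2) of the HCD minus NCD log2 difference, and the median over the 6 genes was 0.463. This median turned negative without HCD 3 (-0.292) or HCD 4 (-0.288), where 1 gene was called. These genes were chosen for their difference in the same HCD and NCD libraries, so the choice favours high HCD and low NCD values. When 50 genes were chosen on part of the HCD and NCD mice and measured in the others, over 40 draws, the median difference was 0.21 for HCD minus NCD (range -0.29 to 0.45) and 0.05 for DS minus NCD (range -0.21 to 0.30). Across 11433 genes, which are not independent replicates, HCD minus NCD correlated with DS minus NCD at r = 0.572, and simulated groups without any effect gave 0.535 because both differences share the NCD libraries. The covariance was 0.0214 against 0.0142 simulated, and with the NCD mice divided between the 2 differences r averaged 0.0908 (range -0.0886 to 0.138 over 10 divisions). HCD minus NCD and DS minus HCD, which share the HCD libraries, correlated at r = -0.541, against -0.437 in the simulated groups. With the HCD mice divided between them r averaged -0.173 (range -0.27 to -0.0238 over 10 divisions). A test for any difference among the 3 groups called 1 gene, Scd2, with 898 genes at an unadjusted p under 0.05.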

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

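Apart from the test with library size, every test below was chosen, or its prediction written, after the result was seen. A mouse far from the others of its group was found for 6 of 114 groups of values examined (gap to the nearest mouse over the group's range above Dixon's 95% value), where chance alone gives about 5.7. Counts out of 100 splits include the real grouping.

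The largest unnamed transcript row took 3.514% of the counts over kept rows (1 per gene) of NCD 4, against 0.41% to 0.943% in the other NCD mice. The heat shock and dissociation stress score was 5.085 in NCD 5, against 5.88 to 6.082 in the other NCD mice, and 6.854 in HCD 6, against 5.313 to 5.877 in the other HCD mice. The B cell score was 4.572 in NCD 1, against 2.134 to 2.663 in the other NCD mice. The dendritic cell score was 3.619 in DS 3, against 2.673 to 2.883 in the other DS mice. The stroma and endothelium score was 5.173 in HCD 4, against 4.616 to 4.753 in the other HCD mice.

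The interferon lists were higher in HCD than in NCD, with median log2 fold changes of 0.22 (type I) and 0.154 (interferon gamma). With library size as a covariate the type I median was 0.224, with B cell and monocyte scores it was 0.187, and with a surrogate variable for other structure the interferon gamma median was 0.103, each with the preset-correlation call kept, which argues against these as the whole cause of that call. With an estimated correlation neither list was called in any fit (type I adjusted p = 0.151 without covariates and 0.124, 0.306 and 0.145 with them in the same order, interferon gamma 0.151 and 0.0833, 0.237 and 0.245). Over 100 splits of the 11 mice, 2 gave an interferon gamma list p as small as the real 1.93e-20 (smallest other 4.54e-24), fewer than the limit of 5 set for chance, but 7 did for the type I list (real 5.63e-24, smallest other 2.44e-33). That limit was set after these counts were seen. Neither score passed its exact permutation test after adjustment (0.390 for type I and 0.227 for interferon gamma, and 0.0433 and 0.0108 before it). A single score could not pass that adjustment over 90 tests alone, so this failure cannot decide. The pattern was found and tested on the same mice, so an accident of which mice fell in which group stays open for both lists. An effect of the diet is one hypothesis. A batch aligned with the diet groups could not be told apart by these fits.

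The cholesterol biosynthesis list was lower in DS than in HCD, with a median of -0.232. It was -0.291 with library size, -0.239 with other-cell scores and -0.229 with the surrogate variable as covariates, with the preset-correlation call kept in each, and 3 of 100 splits gave a list p as small (real 6.59e-14, smallest other 1.44e-19). With an estimated correlation it was called in no fit (adjusted p = 0.174 without covariates, and 0.0511, 0.191 and 0.076 with them in the same order). The covariate medians argue against library size, B cell and monocyte scores and the surrogate variable as the whole cause of the preset-correlation call. A batch aligned with the diet groups could not be told apart by these fits. The score per mouse did not pass its exact permutation test after adjustment (0.227, and 0.00649 before it). A single score could not pass that adjustment over 90 tests alone, so this failure cannot decide. With 3 of 100 splits as small and no call with an estimated correlation, an accident of which mice fell in which group stays open. The diet switch is a hypothesis found and tested on the same mice.

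The follicular helper list was higher in HCD than in NCD, with a median of 0.472 (quartiles 0.155 and 0.821). Library size (0.525) and other-cell scores (0.568) as covariates left the preset-correlation call in place, though with an estimated correlation it was called in no fit (adjusted p = 0.25 without covariates, 0.194 and 0.306 with these), whereas with the surrogate variable the median was -0.00535 (quartiles -0.0474 and 0.0634) and the call ended (adjusted p = 0.871). The variable was estimated from the same libraries and correlates with the list's score within groups (r = -0.815), so this test removes part of what it measures. Of 100 splits, 20 gave a list p as small (real 1.04e-07, smallest other 4.98e-14). A difference between mice that is present within diet groups is therefore a candidate explanation, and whether diet shifts it stays open.

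Chance cannot be excluded for the number of genes called in HCD against NCD or in DS against HCD. Of 100 splits per comparison, 5 called at least the 6 genes of HCD against NCD (highest other 382) and 5 at least the 1 gene of DS against HCD (highest other 35). All 100 splits of DS and NCD reach the count of 0 genes by construction (highest other 4), so this says nothing about chance there. The split with 382 genes set NCD 1 and HCD 1, 2, 3, 4 and 6 against the rest, which is the diet grouping with NCD 1 and HCD 5 exchanged, so it is not free of a diet difference. For the number of lists called, 7 splits reached the 15 of HCD against NCD (highest other 17), 7 the 16 of DS against HCD (highest other 21) and 35 the 9 of DS against NCD (highest other 16).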

How the results depend on the processing

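The surrogate variable, follicular helper score, title number (4 to 6 against 1 to 3), library size, the fit without NCD 4 and DS 2, and the sum over rows and every row of a gene were added as alternatives after the data were seen; the others were set before. Where a value changed below, the cause was not tested. Over 33 alternatives (leaving out the minimum fold change, which ended every call in HCD against NCD, and the fit of every row) none of the 7 gene calls reversed. Scd2 in DS against HCD passed in 33 (log2 fold change -0.7985 to -0.6342). In HCD against NCD, Scd2 passed in 31, Irgm2 in 26, Tgtp2 in 21, Irf9 in 20, Usp18 in 18 and Tnfaip8 in 11. Over all named genes 5699 values kept their side and direction, 62 passed newly, 71 stopped passing and 106 that did not pass changed sign. Of list tests 1968 kept side and direction, 40 were called newly, 199 stopped being called, 122 uncalled ones changed sign and 14 reversed. List scores per mouse kept theirs in 206 cases, and 10 uncalled scores changed sign. Tests of the B cell, monocyte and follicular helper lists with their own score as a covariate were left out as circular, a choice made after some had reversed.

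Called in HCD against NCD (main 6, all higher) were, as total with higher and lower: 0 (0 and 0) with a log2 fold change of at least 0.58; 25 (21 and 4) with DESeq2; 10 (9 and 1) with limma-voom; 14 (10 and 4) with B cell and monocyte scores; 10 (10 and 0) without NCD 4 and DS 2; 1 (1 and 0) with summed rows; 4 (4 and 0) with every row; 2 (2 and 0) with the surrogate variable; and 0 (0 and 0) with the follicular helper score. In DS against HCD (main 1, lower) they were 15 (3 and 12) with DESeq2, 2 (0 and 2) with limma-voom, 2 (1 and 1) with only these groups fitted, 4 (1 and 3) with B cell and monocyte scores, 9 (3 and 6) with library size, and 2 (0 and 2) with the surrogate variable, with the follicular helper score and with the title number (4 to 6 against 1 to 3). In DS against NCD (main 0), DESeq2, the surrogate variable and the follicular helper score gave 1, higher. For any diet difference (main 1) the count was 7 with no filter, 2 without robust estimation, 31 with DESeq2, 5 with limma-voom, 4 with B cell and monocyte scores, 2 without NCD 4 and DS 2, 5 with the surrogate variable, 6 with the title number (4 to 6 against 1 to 3) and 10 with library size.

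With the title number as a replicate block, the calls were 14 (13 higher and 1 lower) in HCD against NCD, 4 (all lower) in DS against HCD, 0 in DS against NCD and 7 for any diet difference. The block gave adjusted p = 0.199 for the type I and 0.0759 for the interferon gamma list in DS against NCD. The numbers were not taken to pair the mice, since not every same-number pair was correlated over 0.1. Over 16 such pairs the correlation of deviations from group means was -0.106 to 0.268 (mean 0.069, against -0.0138 over 80 other pairs), 6 were over 0.1, and 5 of 17 mice correlated best with their own number. The pairs of number 5, singled out after the values were seen, had 0.208, 0.201 and 0.268. The rule that every pair exceed 0.1 is strict, so a pairing or a batch shared by some numbers is not excluded.

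Leaving out each mouse in turn, the calls in HCD against NCD were 0 (without NCD 6) to 19 (without NCD 2), with 0 to 15 higher and 0 to 9 lower. In DS against HCD they were 1 to 4, with 0 higher and 1 to 4 lower. In DS against NCD they were 0 throughout, and for any diet difference 1 to 16. The median share kept in DS (main 0.463) was -0.292 to 0.534, and the correlation of the fitted fold changes (main 0.575) was 0.501 to 0.679. List adjusted p in HCD against NCD was 1.51e-40 to 2.04e-10 (type I), 6.36e-30 to 1.5e-14 (interferon gamma), 4.8e-06 to 0.0433 (cholesterol biosynthesis) and 1.09e-05 to 0.00232 (LXR). In DS against HCD it was 5e-21 to 1.53e-10, 1.26e-14 to 2.92e-08, 6.14e-17 to 3.13e-08 and 1.19e-06 to 0.00026 in the same order. In DS against NCD (main 0.0358, 0.0208, 0.00877 and 0.949) it was 1.05e-07 to 0.89, 4.57e-06 to 0.746, 0.000313 to 0.207 and 0.448 to 0.982, and the type I list reversed without NCD 2 (0.89).

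With an estimated correlation and by fry, the adjusted p-values in HCD against NCD were 0.151 and 0.114 (type I), 0.151 and 0.0837 (interferon gamma), 0.318 and 0.22 (cholesterol biosynthesis), and 0.151 and 0.0837 (LXR). In DS against HCD they were 0.265 and 0.202, 0.174 and 0.114, 0.174 and 0.0874, and 0.17 and 0.0874 in the same order. In DS against NCD they were 0.868 and 0.857, 0.844 and 0.857, and 0.844 and 0.857 for the first 3. The LXR list in HCD against NCD had adjusted p = 0.0624 with the surrogate variable. In DS against NCD the type I list had 0.442 with B cell and monocyte scores and 0.0942 with library size, the interferon gamma list 0.375 with the surrogate variable, 0.471 with the follicular helper score and 0.0942 with library size, and the LXR list 0.318, in the other direction, with B cell and monocyte scores. The mixed test of fry gave adjusted p = 0.00342 (type I), 0.00275 (interferon gamma), 0.169 (cholesterol biosynthesis) and 0.00237 (LXR) in HCD against NCD. Its values in DS against HCD were 0.029, 0.0368, 0.00553 and 2.36e-05 in the same order. In DS against NCD it gave 0.741 for each.

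Lists of helper subsets reversed with the surrogate variable or the follicular helper score. Both were computed from these libraries, so the fits remove part of what they test. The inhibitory receptor list also shares Pdcd1, Tox, Btla, Cd200 and Rgs16 with the follicular helper list. It shares Ctla4, Tigit and Entpd1 with the regulatory list, so these lists are not separate results. With the surrogate variable the adjusted p-values in HCD against NCD were 0.871 (follicular helper), 0.00544 (regulatory) and 0.871 (inhibitory receptors), in DS against HCD 0.991, 0.149 and 0.982 in the same order and 0.917 (naive), and in DS against NCD 0.985 (follicular helper). With the follicular helper score they were 0.0719 (regulatory) and 0.94 (inhibitory receptors) in HCD against NCD, and 0.261 (regulatory), 0.942 (naive) and 0.942 (inhibitory receptors) in DS against HCD. The share kept in DS has no value where no gene was called in HCD against NCD. The shallow libraries (DS 2, 2691946 counts over kept rows) limit the power for low genes.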

Other observations

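The surrogate variable and the 4 relations below were chosen after the results were seen. Within groups, the mice varied in naive, effector and helper-subset genes. On the first principal component (19.4% of the variance), NCD 1 and 2 were at -8.312 and -5.309, and NCD 4 to 6 at 12.8 to 23.04. HCD 1 to 4 were at -24.06 to -10.86, and HCD 5 and 6 at 12.99 and 4.246. DS mice ran from -12.13 (DS 3) to 10.24 (DS 5), with no such split by number. The low side thus held more HCD than NCD mice. No label names a batch, so the cause stays open. A surrogate variable estimated with the diet groups protected was associated with 1330 genes (522 higher and 808 lower, edgeR adjusted p under 0.05). It was estimated from the same values, so a large count is built in and is not comparable with the diet contrasts. Centred within groups, the regulatory T cell (r = -0.83), follicular helper (-0.815), inhibitory receptor (-0.812), Th17 (-0.77), Th1 (-0.728) and effector memory (-0.712) scores ran against it and the naive score with it (0.757). Of the interferon and sterol scores, r was -0.592 for interferon gamma, 0.229 for type I interferon, -0.693 for LXR and 0.348 for cholesterol biosynthesis. These lists contributed to the variable, so the correlations describe it and are not tests. The number in the title, 4 to 6 against 1 to 3, was associated with 51 genes (28 higher and 23 lower).

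Whether the interferon scores vary from mouse to mouse with Th1 or sterol genes was tested over the 17 mice after centring each score within its group, in 4 relations chosen after the scores were seen, with permutation within groups. The interferon gamma score rose with the Th1 score (Pearson r = 0.617, permutation p = 0.0179, adjusted 0.0716; Spearman rho = 0.449, permutation p = 0.0891, adjusted 0.356), which failed the adjustment, and without the 2 mice farthest from the median Th1 score r was 0.478. The type I score did not follow the Th1 score (r = -0.076, permutation p = 0.789, adjusted 0.789; rho = -0.0196, permutation p = 0.946, adjusted 0.946), with an upper 95% limit of 0.454, under the 0.6 taken as a close relation. Without the 2 farthest mice r was -0.265. The 2 interferon lists may therefore differ in what they track between mice, a hypothesis that this number of mice cannot settle.

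No relation of the cholesterol biosynthesis score to either interferon score passed. For the interferon gamma score r was -0.15 (permutation p = 0.563, adjusted 0.769; rho = -0.0417, permutation p = 0.878, adjusted 0.946), with an upper limit of 0.392, and 0.141 without the 2 farthest mice. For the type I score r was 0.13 (permutation p = 0.577, adjusted 0.769; rho = 0.208, permutation p = 0.418, adjusted 0.836), with an upper limit of 0.602, so a close relation is not excluded, and r was 0.445 without the 2 farthest mice.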
